A study of Mus musculus with 6 samples.

How the data were processed

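Ribosome-protected fragments of mouse ID8 cells were measured in 6 libraries, 3 labelled WT and 3 labelled KO, each mapped to its group and replicate number by its title. Per the labels' protocols, cells received cycloheximide (100 µg/mL, 2 minutes) to hold ribosomes in place, RNase I trimmed the unprotected RNA, and a sucrose cushion and then a gel isolated the protected pieces, to which a linker was joined. Per the same protocols, reads were trimmed, those of 25 to 34 nt were kept, reads matching rRNA and tRNA were removed with Bowtie, and the rest were aligned to GRCm38 (mm10) with HISAT2 and to the transcriptome with Bowtie. The submitters' processing notes also name cutadapt, featureCounts and DESeq2, with no versions or roles. The annotation, the strand setting, the treatment of reads with several matches and any removal of duplicates are not given in the sources used here. Short fragments often match several places, so near-identical genes and overlapping genes can share or lose counts.

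The authors deposited a table of whole-number counts per Ensembl gene, with 53465 genes and 1 column per library, not normalized. Of its identifiers 53360 matched GENCODE M21 on GRCm38, from which symbols, gene types, coordinates and coding sequences were taken; the 105 others had at most 12 counts in a library. No column was left without a sample. Total counts ran from 1687466 to 3126208. No molecular identifiers are described and any removal of duplicates is not given, so fragments amplified by PCR may be counted repeatedly. The interval of the log2 fold change of Nat10 includes the spread between libraries.

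The main test was edgeR's quasi-likelihood test (robust, edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM factors and filterByExpr by group, which kept 8200 genes, 8087 of them protein-coding. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, counts scaled to the TMM-adjusted library size, given as mean and SD over 3 libraries, and log2 fold changes are KO minus WT with their standard errors. The common biological coefficient of variation was 0.99. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, lists of at least 5 tested genes, Benjamini-Hochberg over lists), again with an estimated correlation, and with fry. Library composition was compared with an exact two-sided permutation test over 20 assignments, which cannot go below 0.1. No fold is given for genes with at most 3 counts over a group.

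The groups, tests, 28 gene lists and the rule for named genes were fixed at the same stage as the settings below. The rule took Nat10 and the 3 TGF-β ligands, then among called genes with non-overlapping groups, at least 20 CPM in the higher group and a symbol that is not a predicted model the 6 with the largest rise, the 6 with the largest fall and the 4 of each direction with the smallest p. It also took up to 4 tested members of each list with the smallest p. Some genes that the rule took are not named in the text. Genes named outside this rule are marked as chosen after their values were seen. Of the 28 lists 26 had enough tested genes; the lists of leukocyte markers and of fibroblast and endothelial markers had 1 tested gene each.

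The modal count of a library was the peak of its smoothed histogram of gene counts (kernel bandwidth 3, counts from 8 to 150), and molecule equivalents are counts divided by it. Other settings chosen before the data were examined were DESeq2 (1.42.0), limma-voom, DESeq2's size factors or plain library totals in edgeR, no count filter, a filter of 50 counts in 3 libraries, removal of mitochondrially encoded and the 10 most abundant genes, the replicate number as a block, and leaving out each library. Added after seeing the data were molecule equivalents in place of counts, protein-coding genes alone, genes with at least 10 molecule equivalents, removal of each library's trend on coding length and GC, and molecule equivalents thinned to the smallest library (46371).

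The pipeline was tested on simulated counts built from the means and library sizes of these samples, with 200 changed genes of 8200 in each of 10 simulations. It recovered 1.37% of genes changed 2-fold, 19.0% changed 4-fold and 38.5% changed 8-fold, and among genes of at least 200 CPM 10.3%, 85.3% and 100%, with 6.92% false calls. A matrix list raised 1.5-fold was found in 10 of 10 simulations, with 0 of 250 tests of other lists called. Genes were drawn independently there, so this gives no rate of false list calls for genes that vary together. A 2-fold change was thus mostly out of reach at this depth. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and plots.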

Results

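Ribosome profiling sequences the short pieces of mRNA that translating ribosomes shield from nuclease, so the count of a gene reflects both how much of its mRNA is present and how densely ribosomes occupy it. The series applied it to ID8, a cancer line derived from mouse ovarian surface epithelium, to ask how translation differs when NAT10, the acetyltransferase that places N4-acetylcytidine on RNA, is targeted with a guide RNA. There were 6 libraries, 3 labelled WT (control guide) and 3 labelled KO (Nat10 guide). Matched RNA-seq was not used here, so changes in mRNA level and in translation were measured together and no translation efficiency was computed. Total gene counts were 1687466, 2148715 and 1811225 in the WT libraries and 2541273, 2234305 and 3126208 in the KO libraries. Between 8265 and 9437 genes had at least 1 count in a library. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries.

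The counts of genes had a second, local peak far above single reads. The most frequent count above 0 was 1 in every library, held by 490 to 986 genes, and between counts of 8 and 150 the number of genes peaked again at 15, 21 and 39 in the WT libraries and at 42, 46 and 60 in the KO libraries. A count divided by this local peak, the modal count, is called molecule equivalents below. On that scale the libraries held 112498, 102320 and 46442 (WT) and 60506, 48572 and 52103 (KO) in total. Of the 8200 genes tested, 55.7% averaged under 3 molecule equivalents, and replicate libraries correlated across genes at r = 0.623 to 0.705 within WT and 0.571 to 0.602 within KO (log CPM, genes not being independent replicates). Libraries of different groups correlated at 0.543 to 0.630, and each KO library correlated more with WT replicates 1 and 2 than with the other KO libraries, so the libraries did not group by label over all genes. Differences of low-count genes were therefore often not detectable at this depth.

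**Figure D1:**
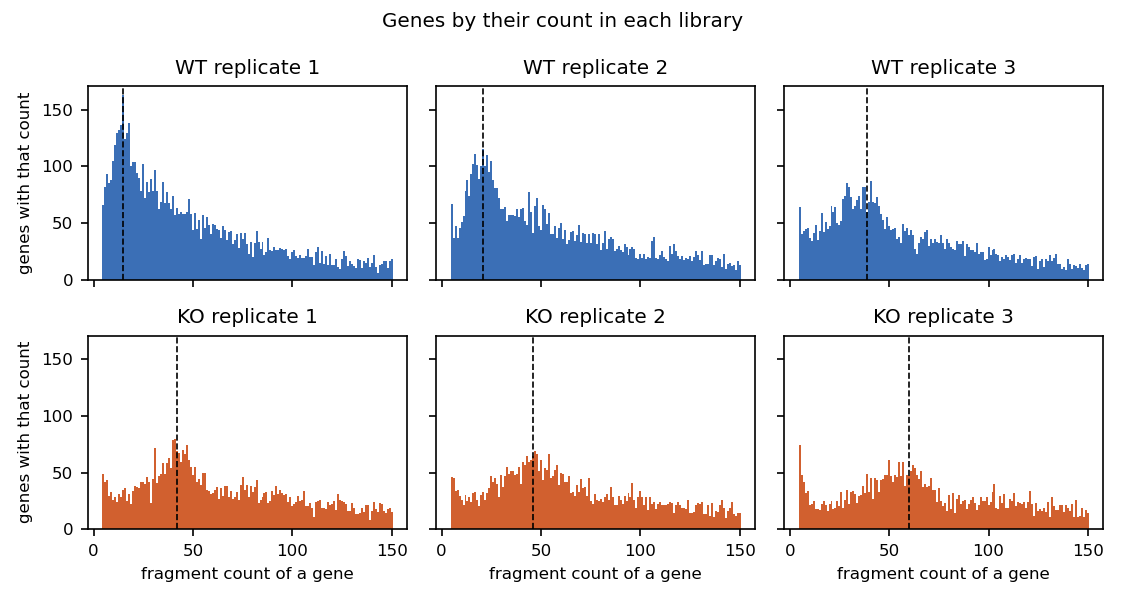
Number of genes (vertical axis) at each fragment count from 5 to 150 (horizontal axis) in each of the 6 libraries, WT above and KO below, with the modal count as a dashed line. The local peak above counts of 8 lies between 15 and 39 in the WT libraries and between 42 and 60 in the KO libraries.

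No difference in Nat10 fragments was detected between the libraries labelled WT and KO. Nat10 (ENSMUSG00000027185, protein-coding, minus strand of chromosome 2, 103721256 to 103761270 in GRCm38) had counts of 168, 128 and 292 in WT and 315, 133 and 445 in KO. Normalised levels were 112 ± 53.1 CPM in WT and 106 ± 43.1 CPM in KO (SD, n = 3). The log2 fold change, KO minus WT, was -0.074 (SE 0.48, 95% interval -1.09 to 0.94; edgeR quasi-likelihood adjusted p = 1.0). Its sign changed under several settings, for example to 0.35 without WT replicate 3 and 0.23 without KO replicate 2. The site cut by the guide is not given in the sources used here, and an edited gene can still give fragments. Directions below therefore refer to the libraries labelled KO and not to a measured loss of Nat10.

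Among the 3 TGF-β ligands, a pathway the series names together with NAT10, none was called. Tgfb1 had counts of 0, 1 and 0 in WT and 2, 0 and 0 in KO and was too low to test. Tgfb2 averaged 27.4 ± 17.2 CPM in WT and 29.8 ± 23.2 CPM in KO, and Tgfb3 44.4 ± 41.7 CPM in WT and 32.2 ± 16.2 CPM in KO (SD, n = 3). Their log2 fold changes were 0.12 (SE 1.13) and -0.46 (SE 0.89), and both signs depended on single libraries, with Tgfb2 at -0.74 without KO replicate 1 and Tgfb3 at 0.66 without WT replicate 2.

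The groups nevertheless differed at 33 genes, 15 higher and 18 lower in the libraries labelled KO. The 2 called genes with the smallest p went in opposite directions. Ankrd1, an ankyrin-repeat nuclear protein (chromosome 19, 36111961 to 36120099), rose from 217 ± 47.9 to 1426 ± 179 CPM (SD, n = 3; log2 fold change 2.72, SE 0.22, edgeR adjusted p = 3.3e-05). Tgm2, a transglutaminase that crosslinks proteins (chromosome 2, 158116402 to 158146436), fell from 250.2 ± 8.19 to 1.66 ± 1.72 CPM (log2 fold change -7.22, SE 0.70, edgeR adjusted p = 0.00021), with counts of 426, 498 and 420 in WT against 0, 8 and 5 in KO, all below the modal counts of the KO libraries, so the size of the fall is uncertain.

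Other higher genes were of varied function. The secreted metalloprotease Adamts1 rose by 2.56 (SE 0.29) on the log2 scale, the lysosomal and surface glycoprotein Gpnmb by 1.93 (SE 0.27), and B2m, the light chain of MHC class I, by 1.47 (SE 0.20). Grem1, a secreted antagonist of bone morphogenetic proteins, had no count in any WT library and 206, 167 and 112 in the KO libraries. It averaged only 1.73 molecule equivalents over the 6 libraries, so no fold is given. Dync1h1, the heavy chain of cytoplasmic dynein, also rose (log2 fold change 1.86, SE 0.35), with 996, 1614 and 3418 CPM in the KO libraries against 448, 468 and 741 CPM in WT.

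Lower genes were also of varied function. Pgm1, a phosphoglucomutase, fell from 455 ± 110.4 to 80.0 ± 8.22 CPM (log2 fold change -2.51, SE 0.29), and the thioredoxin Txn1 from 815 ± 116 to 230.4 ± 22.1 CPM (-1.82, SE 0.22). Gfpt2, an enzyme of hexosamine synthesis, fell by 3.66 (SE 0.71) on the log2 scale. Its KO counts were 110, 4 and 57, and those of KO replicates 2 and 3 lay below their modal counts of 46 and 60. The size of its fall is therefore uncertain, and it was called in 2 of 6 fits without single libraries. Pltp, a phospholipid transfer protein, had 372 counts over the WT libraries and 1 over the KO libraries, and Cyp2j6, a cytochrome P450, 376 and 3. Each KO count of Pltp and Cyp2j6 lay below the modal count of its library, so no fold is given. Pltp averaged only 2.74 molecule equivalents. Hspa5, the chaperone BiP, was the most abundant of these named genes and fell from 4288 ± 249 to 2178 ± 114 CPM (-0.98, SE 0.13, edgeR adjusted p = 0.0040).

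**Figure D2:**
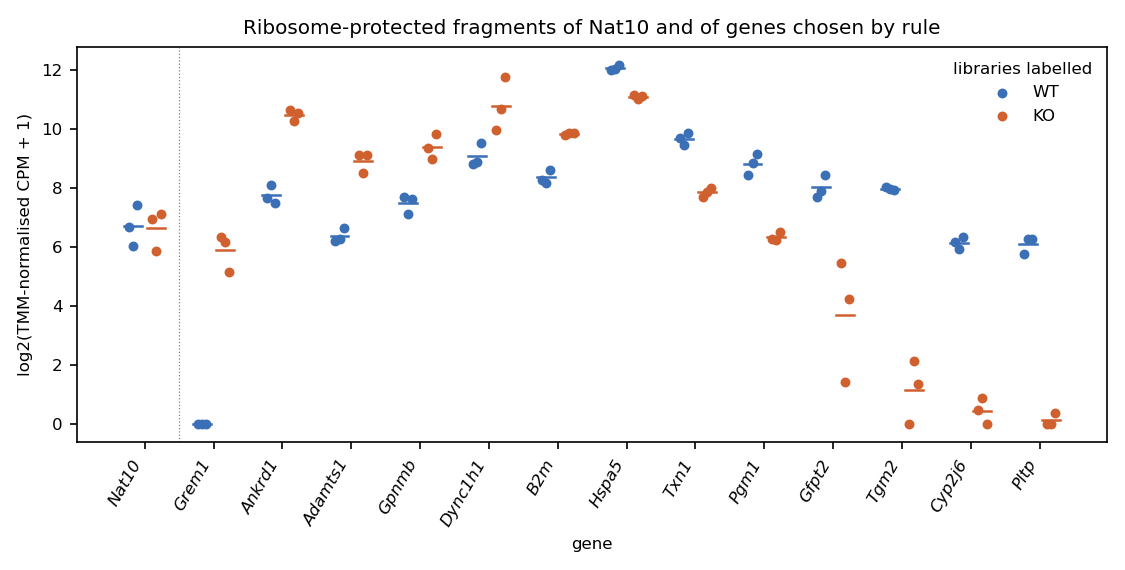
Level of Nat10 and of 13 genes chosen by rule (horizontal axis) as log2 of normalised CPM plus 1 (vertical axis), with a point per library and a bar at the mean of the 3 WT (blue) and 3 KO (orange) libraries. The groups overlap for Nat10, and every KO library lies on the same side of every WT library for the other 13 genes.

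Of the 33 called genes, 28 changed at least 2-fold, 14 in each direction, and for all 33 every KO library lay on the same side of every WT library. That separation held for 14.9% of all tested genes, against 10% by chance with 3 libraries per group. The count moved with single libraries, to 29 without WT replicate 1, 6 without WT replicate 2, 6 without WT replicate 3, 15 without KO replicate 1, 20 without KO replicate 2 and 18 without KO replicate 3. All 33 kept their direction and an unadjusted p under 0.05 in each of these fits that tested them. The 33 were picked on these same libraries and for all of them the groups did not overlap, so this was nearly fixed by their selection. With library totals in place of TMM factors the split was 27 higher and 16 lower, and the median over all tested genes moved by 0.11 on the log2 scale; DESeq2 called 234 genes, 106 higher and 128 lower, among them all 33.

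Of 26 gene lists with enough tested members, 12 stood apart from the other genes by camera with its preset correlation, 5 lower and 7 higher in the libraries labelled KO. None of the 12 held with a correlation estimated for each list, where the lowest adjusted p was 0.135 and 7 lists had an unadjusted p under 0.05. Among the 12, estimates ran from -0.035 for MHC class I presentation to 0.078 for p53 targets. For ER chaperones the estimate was 0.0019, below the preset 0.01, yet camera's unadjusted p rose from 3.4e-06 to 0.0067. For MHC class I presentation camera's unadjusted p rose from 0.0037 to 0.037. With an estimated correlation camera takes its degrees of freedom from the 6 libraries and not from the genes. A lost call therefore does not by itself show strongly correlated members, and this setting had little power with so few libraries. By fry, 12 lists moved in a single direction on balance and 22 held members that changed in either direction. The 12 are not the same lists: fry called immediate early genes (adjusted p = 0.035) and ATF4 targets (0.047), which camera did not, and missed genes induced by TGF-β (0.074) and interferon-stimulated genes (0.085).

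Chaperones of the endoplasmic reticulum and genes of the unfolded protein response were lower as a group by camera with its preset correlation (adjusted p = 8.8e-05), a call lost with an estimated correlation (adjusted p = 0.135). Of 31 tested members 24 had a negative fold change (median -0.64), 3 fell over all genes (Hspa5, Hsp90b1 and Hyou1) and 8 adjusted over the list alone. Of 19 other settings, Hspa5 was called in 17, Hsp90b1 in 12 and Hyou1 in 6. Without single libraries Hspa5 was called in 4 of 6 fits, and Hsp90b1 and Hyou1 in 0. Hsp90b1, the chaperone GRP94, fell from 2805 ± 108 to 1594 ± 53.5 CPM, and Hyou1, which assists BiP, from 459 ± 37.6 to 196 ± 34.4 CPM (SD, n = 3). The secreted ER factor Manf passed adjusted over the list alone (log2 fold change -1.09, SE 0.23). Targets of ATF4, the transcription factor of the integrated stress response, had a median of -0.36 and a mean of -0.059 over 27 tested members. Of these, 10 were positive, and the list was not called by camera (adjusted p = 0.068). Whether the list was called depended on the setting: camera called it lower with the filter of 50 counts in 3 libraries (adjusted p = 0.0012) and on molecule equivalents (0.022), and in none of the other 15 settings, where adjusted p went up to 0.21. Fry, which does not compare a list with other genes, called it lower (adjusted p = 0.047). Of its members 3 fell adjusted over the list alone. These were Ddit4, an inhibitor of mTORC1 signalling (log2 fold change -2.47, SE 0.53), Asns, the asparagine synthetase (-1.41, SE 0.31), and Atf4 itself (-1.09, SE 0.26).

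Cholesterol synthesis genes had negative fold changes in 21 of 23 tested members (median -0.48, camera adjusted p = 0.0014, and adjusted p = 0.135 with an estimated correlation). None passed over all genes, and Fdft1, the squalene synthase, passed adjusted over the list alone (-1.25, SE 0.31). Of 34 proteasome subunits 29 had negative fold changes (median -0.31, camera adjusted p = 0.011, and adjusted p = 0.140 with an estimated correlation), none passing singly. Psmd2, a subunit of the proteasome's regulatory particle, stood at -1.04 (SE 0.27). Replication-dependent histones had a median of -0.59 over 44 tested members, 30 of them negative (camera adjusted p = 0.0033, and adjusted p = 0.140 with an estimated correlation), with none called singly; Hist1h1a stood at -1.20 (SE 0.34) and Hist1h2be at 1.72 (SE 0.58). Histone genes are near-identical copies, so their counts are uncertain for fragments of this length. G2 and M phase genes had a median of -0.25 with 32 of 39 negative (camera adjusted p = 0.043, and adjusted p = 0.140 with an estimated correlation) and no called member; Aurka, a mitotic kinase, stood at -1.07 (SE 0.39). Over genes with at least 10 molecule equivalents the cholesterol, proteasome and histone lists each stood at camera adjusted p = 0.060, and the proteasome list at 0.075 with coding length and GC removed and 0.123 without KO replicate 3. The G2 and M list lost its call in 9 of 17 settings, with adjusted p = 0.051 without WT replicate 1, 0.138 without WT replicate 3, 0.175 without KO replicate 1 and 0.111 without KO replicate 3.

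Targets of p53 were higher as a group, with positive fold changes in 22 of 28 tested members (median 0.73, camera adjusted p = 0.00024, and adjusted p = 0.140 with an estimated correlation). No member passed, over all genes or adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, averaged 31.3 ± 21.3 CPM in WT and 136 ± 16.9 CPM in KO (SD, n = 3, log2 fold change 2.11, SE 0.61). Mdm2, the ubiquitin ligase of p53, averaged 65.2 ± 23.7 CPM in WT and 140.1 ± 26.1 CPM in KO (1.10, SE 0.43). Over the 6 libraries Cdkn1a averaged only 4.92 and Mdm2 6.76 molecule equivalents.

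The mesenchymal list had positive fold changes in 13 of 15 tested members (median 0.39, camera adjusted p = 0.00085, and adjusted p = 0.135 with an estimated correlation). Its members that rose adjusted over the list alone were Cd44, a hyaluronan receptor (0.95, SE 0.21), Lgals1, a galectin (0.61, SE 0.13), Fn1, fibronectin (1.03, SE 0.25), and Vim, the intermediate filament vimentin (0.39, SE 0.13), and none passed over all genes. Extracellular matrix genes had a median of 0.22 over 37 tested members (camera adjusted p = 0.0038, and adjusted p = 0.135 with an estimated correlation). None passed over all genes, and 7 rose and 2 fell adjusted over the list alone. Among the 7 were Lox and Loxl1, enzymes that crosslink collagen (1.59, SE 0.38, and 1.86, SE 0.51), and the proteoglycan Dcn (0.67, SE 0.19).

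Genes induced by TGF-β were higher on balance, with positive fold changes in 16 of 23 tested members (median 0.27, camera adjusted p = 0.011, and adjusted p = 0.146 with an estimated correlation). Among the members that rose adjusted over the list alone were Fn1, Lox and Ccn2, a secreted matricellular protein (231 ± 89.1 CPM in WT and 463 ± 69.5 CPM in KO). Fn1 and Lox are also in the matrix list. The call was lost without WT replicate 3 (adjusted p = 0.084), without KO replicate 3 (0.172) and on thinned molecule equivalents (0.085). The list of TGF-β ligands, receptors and Smads had a median of 0.61 with 20 of 28 members positive (camera adjusted p = 0.011, and adjusted p = 0.140 with an estimated correlation). No member passed over all genes, and Inhba, the activin A subunit (2.83 ± 4.90 CPM in WT and 113 ± 18.4 CPM in KO), and Ltbp1, which binds latent TGF-β (1.02, SE 0.29), rose adjusted over the list alone.

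MHC class I presentation genes had a median of 0.44 over 14 tested members (camera adjusted p = 0.011, and adjusted p = 0.140 with an estimated correlation). B2m rose over all genes, from 329 ± 52.4 to 908 ± 20.9 CPM (SD, n = 3), the heavy chain H2-D1 rose adjusted over the list alone (1.34, SE 0.35), and the ER chaperone Calr, a member of this list and of the chaperone list, fell adjusted over the list alone (-0.70, SE 0.16). Class I heavy chains are close paralogs, so H2-D1 fragments are uncertain. The call was lost without WT replicate 2 (adjusted p = 0.056), WT replicate 3 (0.072) or KO replicate 2 (0.077), and over genes with at least 10 molecule equivalents (0.261). Interferon-stimulated genes had a median of 0.65 over 30 tested members, 22 positive (camera adjusted p = 0.043, and adjusted p = 0.146 with an estimated correlation), with none called singly; Eif2ak2, the kinase PKR, stood at 1.09 (SE 0.48). That call was lost in 7 of 16 settings, with adjusted p = 0.061 without WT replicate 1 and 0.196 without KO replicate 2.

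**Figure D3:**
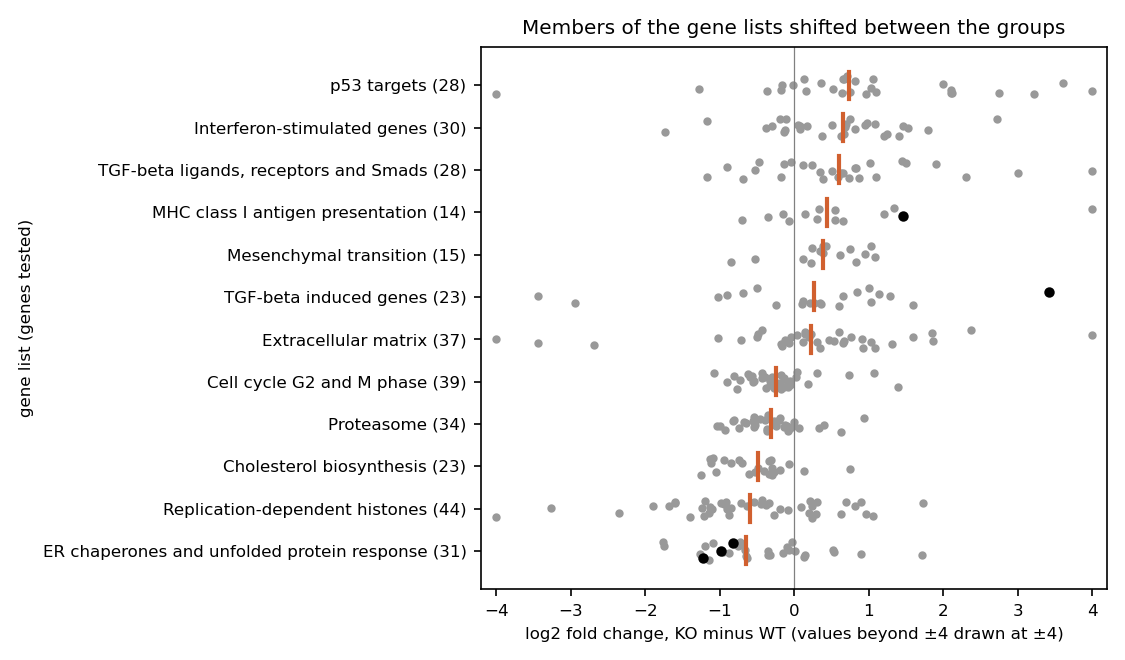
Log2 fold change, KO minus WT (horizontal axis), of each tested member of the 12 lists that stood apart by camera's preset correlation (vertical axis, number of tested genes in brackets), with grey points for members not called over all genes, black points for called members and an orange bar at the median. Medians run from -0.64 for ER chaperones to 0.73 for p53 targets.

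The list of epithelial and mesothelial identity was not called (15 tested, median -0.084, mean 0.29, camera adjusted p = 0.54), and its members went both ways. The keratins Krt19 and Krt18 fell (log2 fold change -0.92, SE 0.13, and -1.74, SE 0.31), and Msln, the mesothelial surface protein mesothelin, rose from 789 ± 83.5 to 1636 ± 209 CPM (SD, n = 3). Over the list alone 3 members rose and 3 fell. The median of this list depended on the setting, from -0.41 on molecule equivalents (camera adjusted p = 0.086), -0.35 with no count filter (0.22) and -0.34 without WT replicate 3 (0.090) to 0.028 with library totals (0.78) and 0.068 without WT replicate 2 (0.75), and it was called in none. Immediate early genes just missed the threshold (median 0.37, camera adjusted p = 0.054, and 0.034 on molecule equivalents), with Fosl2, an AP-1 subunit, higher adjusted over the list alone (1.60, SE 0.42).

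Lists of the translation machinery were not called by camera on the deposited counts, and 3 of the 4 were called lower on molecule equivalents. Cytosolic ribosomal proteins had a median of 0.053 over 76 tested members (camera adjusted p = 0.59; -0.034 on molecule equivalents), ribosome biogenesis genes -0.16 over 67 (0.14), initiation and elongation factors -0.22 over 46 (0.086) and cytosolic aminoacyl-tRNA synthetases -0.20 over 20 (0.17). On molecule equivalents ribosome biogenesis (camera adjusted p = 0.0098), the factors (0.014) and the synthetases (0.031) were called lower, and in the other 16 settings none of the 3 was called. Rps23, a small-subunit protein, was higher adjusted over the list alone (1.40, SE 0.30), although counts of ribosomal protein genes can be shared with processed pseudogenes. Glycolysis and hypoxia genes had a median of -0.19 (camera adjusted p = 0.10, but 0.041 without WT replicate 1 and 0.018 on molecule equivalents), with Pgk1, phosphoglycerate kinase, and Slc16a1, a lactate transporter, lower adjusted over the list alone (-0.98, SE 0.25, and -0.91, SE 0.25). Cytokines and checkpoints had a median of 0.11 and a mean of -0.30 (0.30, but 0.030 and higher over the 5 members with at least 10 molecule equivalents), with Ptgs2, the inducible cyclooxygenase, higher adjusted over the list alone (1.44, SE 0.31). The S phase list stood at -0.20 (0.16, and 0.049 on molecule equivalents), fatty acid metabolism at -0.25 (0.26), nuclear-encoded oxidative phosphorylation at -0.15 (0.59), mitochondrially encoded proteins at -0.13 (0.90) and DNA damage response at -0.011 (0.97), the last turning positive under other scalings (0.014 with DESeq2 size factors).

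Markers of other cell types were mostly too low to test, with Dcn as an abundant exception. Of the leukocyte markers, Cd14 alone was tested, with 115 counts over the 6 libraries, and of the fibroblast and endothelial markers Dcn alone, which the matrix list also holds and which stood at 700.2 ± 35.6 CPM in WT and 1117 ± 188 CPM in KO (SD, n = 3), higher in every KO library than in every WT library. KO replicate 3 stood apart: it had counts for 26 of the 50 markers, 22 of them in no other library, while each other library had counts for 1 to 4. These 22 markers summed to 138 counts, 88 of them from Col3a1, a fibrillar collagen chosen after its values were seen. Over all genes, 688 had counts in KO replicate 3 alone (median count 1), against 248 to 382 in each other library alone. Without KO replicate 3 camera still called the mesenchymal (adjusted p = 0.0018) and matrix (0.011) lists higher. Library composition differed in several measures as far as 3 against 3 libraries can show, with an exact two-sided permutation p of 0.1, the smallest possible. The 10 most abundant genes took 27.8% ± 2.39 of WT and 23.5% ± 1.51 of KO counts. The rRNA-like predicted genes Gm42418 and Gm26917, chosen after their values were seen, took 12.95% ± 0.864 of WT and 10.3% ± 0.640 of KO counts. Gm42418 was itself among the 18 lower genes (-0.51, SE 0.082). Total counts and modal counts were higher in every KO library than in every WT library. Mitochondrial rRNA took 11.5% ± 2.76 of WT and 9.54% ± 2.13 of KO counts (exact permutation p = 0.4).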

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

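Of the settings below, those on molecule equivalents, protein-coding genes, genes with at least 10 molecule equivalents, and coding length with GC were chosen after seeing the data. In every setting that tested them, the 33 called genes kept their direction and an unadjusted p under 0.05. They were picked on these same libraries, so this is no independent support. The count of called genes was 234 with DESeq2 (106 higher, 128 lower, 178 at least 2-fold), 91 with no count filter (49, 42 and 73), 114 on molecule equivalents (42, 72 and 92), 75 among genes with at least 10 molecule equivalents (41, 34 and 50), 51 on thinned molecule equivalents (27 higher), and with library totals 27 higher; the cause was not tested. Leaving out single libraries gave 6 to 29 called genes, 3 to 15 higher, 3 to 14 lower and 6 to 25 at least 2-fold, fewer libraries being fitted. Limma-voom gave 43 and the other edgeR settings 25 to 43. Shifted lists numbered 0 with an estimated correlation, where the degrees of freedom come from the libraries, and 19 on molecule equivalents. They numbered 5 among genes with at least 10 molecule equivalents (fewer genes tested) and 9 to 11 without single libraries. ER chaperones, the mesenchymal list and extracellular matrix kept their call in all 17 edgeR settings with the preset correlation. The lists of p53 targets and TGF-β ligands kept theirs in the 16 of these settings that tested them.

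Nat10 was not called in any setting, and its log2 fold change turned to 0.019 with limma-voom, 0.026 with library totals, 0.077 on molecule equivalents and 0.32 on thinned ones, with -0.35 to 0.35 without single libraries; it had no value among genes with at least 10 molecule equivalents, being below that. Without single libraries Tgfb2 ranged from -0.74 to 0.75 (-0.081 on thinned molecule equivalents), Tgfb3 from -0.95 to 0.66 and mt-Nd5 from -0.79 to 0.54, none of them called; the KO minus WT difference in genes with counts of 1 to 9 ranged from -77.8 to 246, and that in the mitochondrial protein share from -0.054 to 0.064 percentage points. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.017, -0.0026 and -0.0067. With the replicate block 38 genes were called, 19 higher and 19 lower, 34 at least 2-fold, and 10 lists shifted, with Nat10 at -0.064. Camera was not run on the DESeq2 and limma-voom fits. Depth limited the calls: 3 of 4569 tested genes under 3 molecule equivalents were called, and 17 of 296 with 30 or more.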

Other observations

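Of the tests below, the thinned and the length and GC settings, the count of genes with 1 to 4 counts, the interval of Nat10, the comparison of chromosome 2 and the permuted gene order were chosen after the result was seen. Genes named here outside the rule were chosen after their values were seen. Among the other genes higher in the libraries labelled KO were Anxa1, an annexin (3287 ± 269 to 5814 ± 909 CPM, SD, n = 3), Bmper, a secreted regulator of bone morphogenetic proteins (log2 fold change 1.85, SE 0.30), the matrix-associated Aebp1 (1.13, SE 0.21) and Olfml2b (1.10, SE 0.21), the complement protease C1s1 (1.60, SE 0.30) and the membrane protein Plxdc2 (1.83, SE 0.36). Among the others lower were the detoxifying enzymes Gsta4 (-1.37, SE 0.21) and Aldh2 (-1.24, SE 0.22), the complement component C3 (-1.51, SE 0.28), the tetraspanin Tspan8 (-1.21, SE 0.23) and the kinase Jak1 (-1.72, SE 0.35).

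Lower genes lay together on chromosome 4. Txn1 lies at 57943373 to 57956411 and Cyp2j6, Pgm1 and Jak1 between 96516138 and 101265282, and every called gene of this chromosome was lower, which was noticed among the called genes. A candidate explanation is that the cells labelled KO carry fewer copies of these segments, which would lower neighbouring genes too. The 19 other tested genes within the clusters and 1 Mb on each side had a median log2 fold change of -0.70, with 15 of 19 negative, and 0.37% of 10000 random sets of neighbouring genes had a median as low. A scan of windows of 15 genes was then designed after these values were seen, with no other window size tried. With gene order permuted 1000 times, the window of 15 genes from 54945048 to 59618689 on chromosome 4 lay farthest from 0 of 7906 windows (14 of 15 genes lower, median -1.24, permutation p = 0.001, the smallest these permutations can give), which argues against chance placement. The next windows were also lower ones on chromosome 4, from 35191285 to 41275144 (15 of 15 lower, permutation p = 0.046) and from 96516138 to 101659364 (13 of 15 lower, permutation p = 0.054).

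Without the called genes, the first of these segments held 0.291% ± 0.0164 of protein-coding counts in the WT and 0.147% ± 0.0353 in the KO libraries (SD, n = 3), 49.7% less; the segment from 35191285 held 29.6% less. The segment from 96516138 held 0.0645% ± 0.0253 in WT and 0.0397% ± 0.00412 in KO, 38.4% less, but 20.7% less without WT replicate 3, so its loss rests largely on that library. These segments were chosen for being low, which makes their losses look larger. Loss of copies of the segments is thus consistent with the median of -0.70, but genomic copy number was not analysed here, neighbours can be regulated together, and the near absence of Cyp2j6 fragments exceeds the loss of its neighbours. A difference between cell populations that arose apart from Nat10 and an effect of the Nat10 guide stay open, since both run with the label. Chromosome 2 also held more called genes than its share (6 against 2.59 expected, Fisher's exact p = 0.041, adjusted p = 0.49 over 19 chromosomes). There the median of genes with at least 10 molecule equivalents differed from that of other chromosomes by -0.065, which argues against a copy-number difference of the whole chromosome.

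The local peak of the counts may come from PCR copies of few original fragments. Counts drawn by chance from molecule equivalents predict the genes at 0 in a library from the total over its group. Molecule equivalents were rounded to whole numbers here, so a gene at 0 can still hold reads, at a count below the modal count. Over genes with 3 to 30 molecule equivalents in a group, such zeros were 0.991 times that prediction over the 6 libraries (0.890 to 1.13 in single libraries). Taken as independent reads, the counts predict practically no gene without reads, but observed genes without reads were not set against that prediction. WT replicate 3 had 1419 of 5989 such genes at 0 on this rounded scale against 1431 predicted. A minimum count set by the authors is argued against, since every library held at least 840 genes with counts of 1 to 4. The local peak was present in every WT library too (at counts of 15, 21 and 39), so it was not confined to KO. The ratio for zeros in KO was 0.948 times that in WT, but each library was first scaled by its own modal count. That ratio thus cannot tell whether the KO libraries hold fewer original fragments. If the peak comes from PCR copies, a gene at 100 CPM rests on only a few fragments in some libraries, and no biological explanation was tested.

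The level of Nat10 does not separate the groups, and too few fragments could hide a moderate loss. Nat10 averaged 7.10 molecule equivalents per library, and the lower bound of its 95% interval was -1.09, so a 2-fold loss stays possible while a loss well beyond that does not at this spread. An exchange of libraries between the groups is argued against, because each of the 9 splits that exchange 1 WT and 1 KO library called 0 genes with edgeR against 33 for the labelled split. An edit that leaves the mRNA and its fragments in place was not tested, and a wrong label on a whole group leaves no trace in these tests.

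The 33 called genes were set against 3 technical readings. On molecule equivalents thinned to the same total, the median absolute log2 fold change of the 33 was 0.932 of its value. All 33 kept their direction and 28 were still called. Random thinning keeps the expected ratio between groups, and the 33 were picked on the same counts. Thinning therefore cannot decide on a difference in library complexity. The Spearman rho of log2 fold change across genes was 0.058 with coding length and 0.011 with GC content. There was thus little trend to remove. A genome-wide trend on them is argued against, with a ratio of 0.948 after each library's trend was removed. All 32 genes that have a coding sequence kept their direction, and 26 of them were still called. In that setting 20 genes were called higher and 13 lower, and 9 lists shifted. Of the 10 splits of the 6 libraries, 1, the labelled split, gave as many genes (33, against at most 0 in the others), and 10 splits are too few for a share under 0.05. The difference between groups may be one between the cells, as a hypothesis. Library complexity is not excluded, and the guide and any other difference between the cultures run together.

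NAT10 also acetylates leucine and serine tRNAs, so fragments might shift with codon content. Across 8072 genes with a coding sequence, which are not independent replicates, the Spearman rho of log2 fold change with the share of leucine and serine codons was 0.054. That is farther from 0 than in the other 9 splits (at most 0.039 in size) and under the 0.1 set beforehand as the least size to count, so the hypothesis found no support at the level of whole genes. Reads at single codons were not analysed here.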
